A study of Drosophila melanogaster with 6 samples.

How the data were processed

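The analysis used 6 RNA-seq libraries of 3 groups with 2 biological replicates each, per the labels. Gene counts are whole numbers per FlyBase gene as deposited, made by the authors before deposition, and no scaling had been applied to them. The deposited comparison files give, per the file headers, a signal for each group, the mean of counts divided by DESeq size factors. They also give a ratio (fold change) of the authors' group means, with the other group over fat body control. The deposited log2 values are the binary logarithm of that fold change, per the file headers. Each deposited p-value, unadjusted and adjusted, was computed by the authors, and the method of adjustment is not given in the file headers. TopHat, HTSeq, DESeq and the genome build dm3 are named per the submitters' processing notes, without versions. The counting mode, the strand setting and the annotation release are not given in the sources used here, so values of multi-copy, overlapping or antisense genes are uncertain. Nothing upstream of the counts was rerun.

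Of 14869 gene identifiers, 13532 were given a symbol from gene tables of the release 6 reference, 8 of them through RefSeq synonyms, and 1337 kept their identifier. Those without a symbol took 4.63% to 14.5% of a library's counts, and 1295 genes had no count in any library. Gene lists were matched by symbol or synonym: the 36 lists held 1024 members found in the table, and 83 members were not matched. The lists cover fat body functions, neurons, glia and neuroblasts, cell division, chromatin, hormone, stress and detoxification responses, ribosomes and mitochondria, and 11 of them hold markers of tissues that a dissection could carry along.

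Genes were kept by filterByExpr on the 3 groups, which left 10029. Counts were scaled by TMM and fitted with edgeR (estimateDisp and glmQLFit, both robust, with default settings, then glmQLFTest) over all 6 libraries with group as the only term, which leaves 3 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and list members were also adjusted over the list alone. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over all lists of a comparison, with camera at an estimated correlation and fry as second readings. Values per gene are CPM over TMM-scaled library sizes, and SD is between the 2 replicates. Correlations between libraries used log2 CPM with a prior count of 2. A fold against a group without counts is a lower bound over a floor of 3 counts per group. With 1 to 3 counts in a group the ratio has a 95% counting interval, and both the floors and the intervals cover counting error only. DESeq2 was run on the same counts with its own size factors and filtering.

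The tests, the lists, most alternative settings and the rule for naming genes were fixed before the data were examined. For each comparison the rule took the 6 largest differences in each direction among called, separated genes with a symbol and at least 10 CPM in the higher group. It also took up to 3 called members of each list by size of difference, or the member with the smallest p where none was called, and the 2 most abundant members of each list of other tissues. The fusion partner genes Pc, HP1, MRG15, brm and His1, and EcR, elav, repo, Lsp2, roX1 and roX2 were always taken. The text leaves out some of these genes. Genes outside this rule were named after their values were seen: the DESeq2 calls with 4-HT, genes called without single libraries, Hml, Fbp1, atilla, fkh and the glue protein gene Sgs3, and single genes in the closing section. The alternative with legacy=TRUE equals the default of this edgeR version, and legacy=FALSE was added after seeing the data. Fits without 1 library leave a group with a lone sample, which is assumed to vary like the other groups.

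A self-test simulated negative binomial counts with the scaled library sizes and gene-wise dispersions of the data and 50 changed genes at each of 4 fold sizes. Each gene was drawn independently, so the simulated lists held no correlation between genes. In the tissue comparison edgeR (9743 genes run) recovered 0%, 22.0%, 92.0% and 96.0% of genes changed 1.5-fold, 2-fold, 4-fold and 16-fold, with 14 false calls among 9543 unchanged genes. In the 4-HT comparison edgeR (9829 genes run) recovered 2%, 28.0%, 82.0% and 94.0%, with 12 false calls among 9629. DESeq2 (10029 genes run) recovered 2%, 42.0%, 94.0% and 98.0% in the tissue comparison and 10%, 48.0%, 88.0% and 98.0% in the 4-HT comparison, each with 33 false calls among 9829 unchanged genes. With both tools and in both comparisons the false share of all simulated calls was above the adjusted p threshold of 0.05. A simulated changed list was called by camera with the preset correlation (adjusted p = 2.58e-20 and 1.10e-18) and by fry (0.00553 and 0.0139), and missed with an estimated correlation (0.0680 and 0.0770). Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.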

Results

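Polyadenylated RNA was sequenced from tissues of male wandering L3 larvae of Drosophila melanogaster raised at 25 °C. The 6 libraries fell into 3 groups of 2 biological replicates each: central brain, fat body, and fat body of larvae raised on food with 25 µM 4-hydroxytamoxifen (4-HT). The fat body is the larval organ of nutrient storage and detoxification and a source of antimicrobial peptides. Each library pooled larvae of 6 transgenic lines in equal numbers, 30 larvae for brain and 18 for fat body. The lines carry a Dam methyltransferase gene with a 4-HT-dependent intein, alone or fused to the gene of a chromatin protein (PC, H1, HP1, MRG15 or BRM). Total counts were 20687696 and 26530280 in the brain libraries, 25860088 and 50905534 in the fat body control libraries, and 47054569 and 65802288 in the fat body 4-HT libraries. In every fat body library the larval serum protein genes Lsp2, Lsp1beta and Lsp1gamma and the receptor gene Fbp1 were among the 5 most abundant genes. Those 5 genes took 47.0% to 51.6% of the counts. The 5 most abundant genes of a brain library took 4.20% and 5.52% of its counts. The widest 95% Wilson interval of these shares was 0.0385 percentage points and covers counting error only, while the shares of the control fat body replicates were 48.7% and 51.6%.

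Brain and fat body libraries lay at opposite ends of the first principal component, which held 92.0% of the variance of log2 CPM. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.985 between the brain replicates, 0.9645 between the fat body control replicates and 0.979 between the 4-HT replicates. Fat body control replicate 1 correlated at 0.9608 and 0.9666 with the 4-HT libraries, and control replicate 2 at 0.9835 and 0.9812. Between the control replicates 15.8% of tested genes differed over 2-fold, and between the 4-HT replicates 12.7%. Salivary gland genes were far higher in control replicate 1, and whether they account for its lower correlations was not tested. The 20 members of the salivary gland list in the count table, tested or not, summed to 2032.5 CPM in this library. The sums were 5.28 CPM in control replicate 2, 4.97 and 5.05 CPM in the 4-HT libraries, and 112.8 and 44.1 CPM in brain. In brain most of the second sum came from fkh (40.3 and 41.1 CPM), while glue protein genes were higher in brain replicate 1 than in brain replicate 2, with Sgs3 at 20.4 and 0.0990 CPM, Sgs5 at 14.4 and 0.0990 CPM and Sgs7 at 14.1 and 0.0866 CPM. The hemocyte gene Hml also stood at 48.6 CPM in control replicate 1 against 16.2 CPM in control replicate 2.

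The first comparison asked which transcripts differ between larval brain and fat body. Genes of neurons, synapses, neural progenitors and cell division were higher in brain. Genes of larval serum proteins, lipid, sugar and amino acid metabolism, detoxification and humoral immunity were higher in fat body. Of 10029 genes tested, 7018 (70.0%) changed at an edgeR adjusted p under 0.05, of which 3558 were higher and 3460 lower in brain. The fold was at least 4 for 2040 higher and 1846 lower genes, and at least 32 for 867 and 779. Both replicates of one tissue lay above both of the other for 86.5% of tested genes, against 33.3% by chance.

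Neuronal genes were higher in brain. Of 27 tested members of the neuronal and synaptic list, 26 were higher and 1 lower in brain, with a median log2 fold change of 5.30 (camera adjusted p = 1.51e-08; adjusted p = 0.275 with an estimated correlation). The synaptic vesicle gene nSyb (FBgn0013342) stood at 64.5 ± 2.11 CPM in brain (mean ± SD, n = 2, as in all such values). It had 3 counts in the control fat body libraries together, a ratio of 921 with a 95% counting interval of 315 to 4468. Appl (FBgn0000108), the fly homologue of the amyloid precursor protein gene, stood at 312 ± 20.5 CPM in brain and 0.955 ± 0.324 CPM in fat body. The RNA-binding protein genes fne (FBgn0086675) and elav (FBgn0260400), markers of neurons, stood at 152 ± 3.47 and 225 ± 29.5 CPM in brain against 0.593 ± 0.281 and 1.85 ± 1.03 CPM in fat body. In the list of neurotransmitter synthesis, transport and neuropeptide genes, 26 of 27 members were higher and 1 lower, with a median of 6.25 (adjusted p = 1.20e-09; adjusted p = 0.260 with an estimated correlation). Its summed level was lower in brain, at 583.6 and 564.8 CPM against 938.9 and 1092 CPM in control fat body. As a share of unscaled counts the sum was higher in brain, at 0.168% and 0.172% against 0.0550% and 0.0598%. The vesicular glutamate transporter gene VGlut (FBgn0031424) stood at 114.5 ± 5.32 CPM in brain and 0.243 ± 0.0630 CPM in fat body. The insulin-like peptide gene Ilp3 (FBgn0044050) stood at 11.6 ± 0.450 CPM in brain and had 1 count in fat body, a ratio of 502.5 with an interval of 90.1 to 19858.

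Neural progenitor genes were higher in brain as well. Of 33 members of the neuroblast list, 30 were higher and 1 lower, with a median of 6.51, or 6.07 with the 3 members that had no count in control fat body set to their bound (adjusted p = 1.20e-09; adjusted p = 0.260 with an estimated correlation). The Notch target E(spl)mdelta-HLH (FBgn0002734) and the proneural gene l(1)sc (FBgn0002561) were at least 67.3-fold and 47.7-fold higher in brain, over a floor of 3 counts per group. The forkhead transcription factor genes slp2 (FBgn0004567) and slp1 (FBgn0003430) were among the 6 largest rises, at 23.02 ± 3.63 and 13.55 ± 2.44 CPM in brain and 1 count each in fat body. Their ratios were 973 (95% counting interval 175 to 38458) and 572 (102.5 to 22593). The glia list was split: 10 of 20 members were higher and 3 lower in brain, with a median of 0.87 (adjusted p = 0.0153; adjusted p = 0.260 with an estimated correlation). The list summed to 968.3 and 867.6 CPM in brain against 1259 and 1497 CPM in control fat body. As a share of unscaled counts the sums were 0.279% and 0.264% against 0.0738% and 0.0820%. The camera call was lost without brain replicate 1 (median 0.85, adjusted p = 0.0719), and its adjusted p lay between 0.00957 and 0.0719 over the preset-correlation alternatives. The glial transcription factor gene repo (FBgn0011701) stood at 35.8 ± 2.87 CPM in brain and 0.321 ± 0.200 CPM in fat body. For the glutamate transporter gene Eaat2 (FBgn0026438) the values were 64.4 ± 4.63 and 0.179 ± 0.254 CPM.

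Cell division genes were higher in brain. In the mitosis list 25 of 26 members were higher and 0 lower, with a median of 5.30, or 5.23 with 1 member at its bound (adjusted p = 1.51e-08; adjusted p = 0.320 with an estimated correlation). In the DNA replication list 22 of 23 were higher and 0 lower, with a median of 2.81 (adjusted p = 6.09e-07; adjusted p = 0.297 with an estimated correlation). The cyclin gene CycB3 (FBgn0015625) stood at 52.8 ± 6.16 CPM in brain and 1.025 ± 0.790 CPM in fat body. The replication clamp gene PCNA (FBgn0005655) stood at 72.8 ± 10.6 and 3.47 ± 2.57 CPM. The centromeric histone gene cid (FBgn0040477) was at least 37.6-fold higher in brain.

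Chromatin genes were higher in brain by smaller folds. In the Polycomb group list 17 of 19 members were higher and 1 lower, with a median of 1.65 (adjusted p = 7.22e-04; adjusted p = 0.473 with an estimated correlation). In the list of heterochromatin and chromatin remodelling genes 23 of 26 were higher and 1 lower, with a median of 1.69 (adjusted p = 1.80e-04; adjusted p = 0.275 with an estimated correlation). The Polycomb group gene ph-p (FBgn0004861) stood at 119 ± 2.13 CPM in brain and 9.80 ± 1.26 CPM in fat body. The lamin genes went opposite ways: Lam (FBgn0002525) stood at 340 ± 53.0 CPM in brain and 19.1 ± 3.22 CPM in fat body, and LamC (FBgn0010397) at 2.09 ± 0.742 and 42.05 ± 8.04 CPM. Of the genes fused to Dam in the lines, the HP1 gene (FBgn0003607), Pc and brm were higher in brain, with log2 fold changes of 2.385, 2.04 and 1.83. MRG15 stood at 18.5 ± 1.46 CPM in brain and 14.1 ± 1.31 CPM in fat body, a log2 fold change of 0.40 that did not pass (edgeR adjusted p = 0.0566, and 9.93e-06 to 0.730 over the alternatives). Reads of the fusion transgenes cannot be separated from those of the endogenous genes in these counts. The 23 His1 gene copies had 0 counts in every library, so that H1 was not measured.

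By list median, larval serum protein genes led the lists higher in fat body. All 11 tested members of their list were lower in brain, with a median log2 fold change of -11.77 (camera adjusted p = 1.38e-09, and 0.246 with an estimated correlation). The storage protein genes Lsp2 (FBgn0002565) and Lsp1beta (FBgn0002563) stood at 245461 ± 36169 and 202693 ± 11457 CPM in fat body against 56.4 ± 22.6 and 40.2 ± 17.6 CPM in brain. Of 29 humoral immunity genes 27 were lower and 0 higher in brain, with a median of -6.23, or -5.65 with 4 members at their bound (adjusted p = 1.61e-07; adjusted p = 0.260 with an estimated correlation). The stress and immune response gene TotA (FBgn0028396) stood at 5727 ± 2399 CPM in fat body and 2.28 ± 1.62 CPM in brain. The immune-induced peptide gene BomS3 (FBgn0040736) was at least 190.4-fold lower in brain. The 6 largest falls included Idgf5 (FBgn0064237), of the imaginal disc growth factor family, at 272.7 ± 26.9 CPM in fat body and 0.0415 ± 0.01125 CPM in brain, and Srg3 (FBgn0053926), at least 2126-fold lower in brain.

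Metabolic genes were higher in fat body. In the lipid synthesis and storage list 14 of 16 members were lower and 1 higher in brain, with a median of -2.60 (adjusted p = 1.19e-04; adjusted p = 0.358 with an estimated correlation). The adipokinetic hormone receptor gene AkhR (FBgn0025595) and the perilipin gene Lsd-1 (FBgn0039114) stood at 264 ± 57.6 and 2856 ± 14.3 CPM in fat body and 0.0729 ± 0.0156 and 2.12 ± 0.250 CPM in brain. In the list of carbohydrate and amino acid metabolism 23 of 25 were lower and 1 higher, with a median of -3.64 (adjusted p = 1.35e-10; adjusted p = 0.260 with an estimated correlation). The phenylalanine hydroxylase gene Hn (FBgn0001208) and the trehalose synthesis gene Tps1 (FBgn0027560) stood at 1106 ± 77.9 and 920.3 ± 88.6 CPM in fat body against 0.268 ± 0.0938 and 0.298 ± 0.208 CPM in brain. In the insulin and nutrient response list 21 of 27 were lower and 4 higher, with a median of -3.28 (adjusted p = 2.38e-05; adjusted p = 0.275 with an estimated correlation). Thor (FBgn0261560), the translation repressor 4E-BP, stood at 1962 ± 191.7 CPM in fat body and 2.48 ± 0.0572 CPM in brain.

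Detoxification genes were higher in fat body. Of 62 cytochrome P450 genes, 52 were lower and 3 higher in brain, with a median of -5.05 (adjusted p = 3.02e-12; adjusted p = 0.260 with an estimated correlation). Cyp4s3 (FBgn0030615) stood at 219.6 ± 26.1 CPM in fat body and 0.0517 ± 0.0494 CPM in brain. Of 38 glutathione transferase and UDP-glycosyltransferase genes, 29 were lower and 3 higher, with a median of -4.18, or -4.085 with 3 members at their bound (adjusted p = 6.20e-05; adjusted p = 0.473 with an estimated correlation). GstE3 (FBgn0063497) stood at 396 ± 88.7 CPM in fat body and 0.457 ± 0.0532 CPM in brain. Of 23 xenobiotic regulator and efflux transporter genes, 18 were lower and 1 higher, with a median of -3.04 (adjusted p = 2.37e-04; adjusted p = 0.260 with an estimated correlation). The 1 higher gene was Mdr65 (FBgn0004513), a transporter of the glial blood-brain barrier that the glia list also holds. It stood at 67.4 ± 8.77 CPM in brain and 0.4105 ± 0.0729 CPM in fat body.

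**Figure D1:**
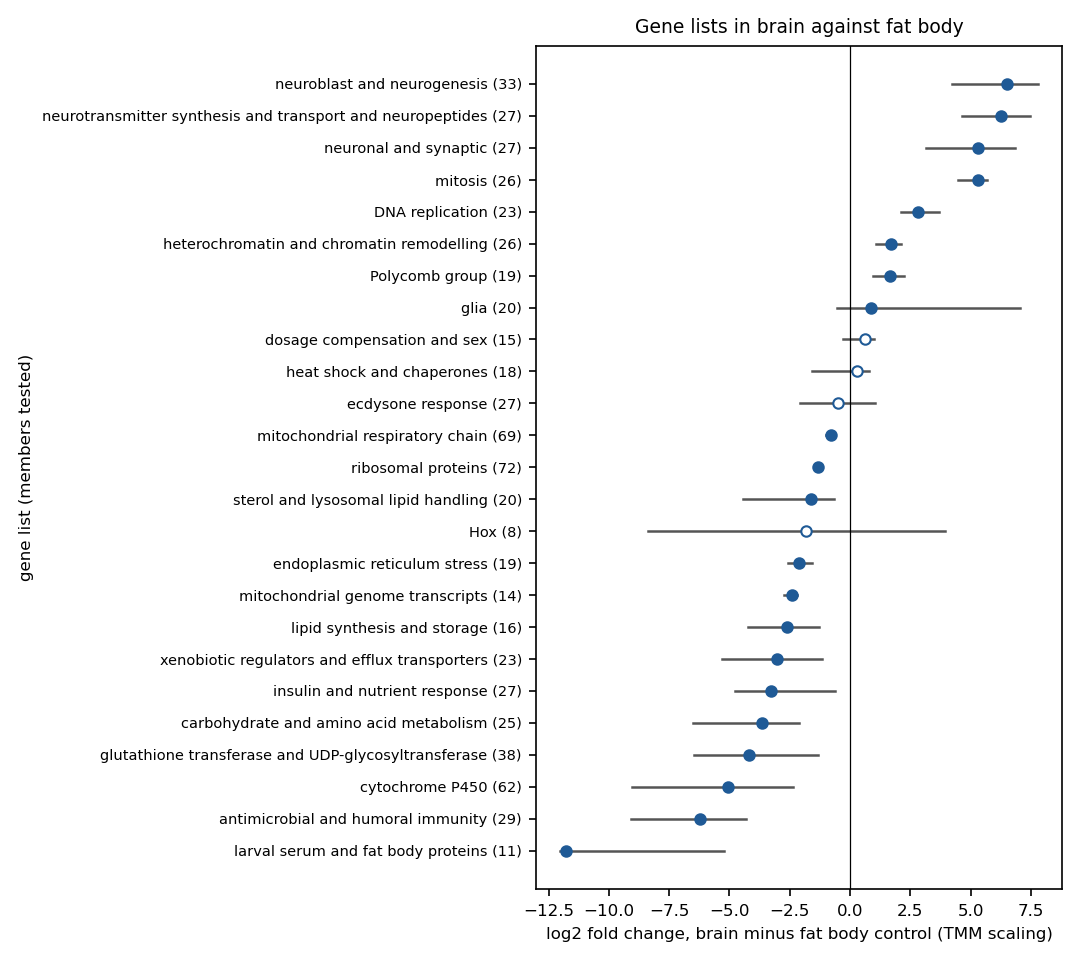
Median log2 fold change (TMM scaling, brain minus fat body control) of each fixed gene list apart from the 11 lists of other-tissue markers, with the number of tested members in brackets. Lines span the quartiles of the members, and filled points passed camera with a preset correlation. Neuronal, progenitor and cell division lists lie to the right and fat body lists to the left. With library size as the only scaling the medians of the ribosomal, respiratory chain, endoplasmic reticulum stress, sterol, ecdysone and Hox lists change sign. Those of the muscle and cuticle lists, which are not plotted, also change sign.

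For secretory, sterol and housekeeping lists the median moved with the scaling between tissues. A change of scaling shifts the log2 fold changes of all genes by nearly the same amount. The place of a list relative to the median of all genes is therefore kept by construction and does not test these results. Relative scaling factors (TMM) were 2.88 and 3.05 for the brain libraries and 0.547 to 0.6145 for the fat body libraries. The median log2 fold change of all genes was 0.11 with TMM, 0.44 with upper quartile scaling and 2.49 with library size only. Of 72 ribosomal protein genes 69 were lower and 0 higher in brain, with a median of -1.32 (adjusted p = 7.97e-05; adjusted p = 0.635 with an estimated correlation), but with library size only 67 were higher and 0 lower (median 1.07, camera adjusted p = 0.149). Over the preset-correlation alternatives its adjusted p lay between 1.31e-09 and 0.149 (camera). Of 69 respiratory chain genes 45 were lower and 1 higher, with a median of -0.80 (adjusted p = 0.0361; adjusted p = 0.818 with an estimated correlation), but with library size only 67 were higher and 0 lower, with a median of 1.57. The camera call was lost without fat body control replicate 1 (median -0.58, adjusted p = 0.241), and its adjusted p lay between 5.54e-04 and 0.518 over these alternatives. Relative to the median of all genes, the medians with TMM and with library size only were -1.425 and -1.42 for ribosomal proteins, -0.91 and -0.91 for the respiratory chain and -2.51 and -2.52 for the mitochondrial genome. They were -2.23 and -2.23 for endoplasmic reticulum stress and -1.74 and -1.73 for sterol genes. Of 14 mitochondrial genome transcripts 13 were lower and 0 higher, with a median of -2.40 (adjusted p = 0.0159; adjusted p = 0.608 with an estimated correlation), and with library size only 0 passed and the median was -0.03. In the endoplasmic reticulum stress list 18 of 19 were lower and 0 higher, with a median of -2.125 (adjusted p = 2.99e-05; adjusted p = 0.260 with an estimated correlation), but 0.25 with library size only. In the sterol and lysosomal lipid list 16 of 20 were lower and 4 higher, with a median of -1.63 (adjusted p = 0.00531; adjusted p = 0.260 with an estimated correlation), but 0.76 with library size only. The chaperone gene Hsc70-3 (FBgn0001218) stood at 3126 ± 250.6 CPM in fat body and 405 ± 63.4 CPM in brain. The sterol-binding protein gene Npc2g (FBgn0039800) stood at 936 ± 35.9 and 0.149 ± 0.0688 CPM.

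Hormone, heat shock and dosage compensation genes went both ways, and their lists did not pass. In the ecdysone response list 6 of 27 members were higher and 9 lower in brain (median -0.50, camera adjusted p = 0.518; with library size only the median was 1.91). ImpE1 (FBgn0001253) stood at 114 ± 17.4 CPM in brain and 0.812 ± 0.438 CPM in fat body. The ecdysone receptor gene EcR (FBgn0000546) stood at 60.8 ± 18.3 and 243 ± 111 CPM, with a log2 fold change of -1.997, or 0.41 with library size only. In the heat shock list 2 of 18 were higher and 4 lower (median 0.27, camera adjusted p = 0.991). Hsp67Ba (FBgn0001227) stood at 178 ± 13.1 CPM in brain and 1.76 ± 0.309 CPM in fat body. In the dosage compensation and sex list 8 of 15 were higher and 2 lower (median 0.61, camera adjusted p = 0.457). The male X chromosome RNA lncRNA:roX2 stood at 30.05 ± 2.38 CPM in brain and 6.59 ± 0.849 CPM in fat body. For lncRNA:roX1 the levels were 774 ± 4.95 and 685 ± 376 CPM (edgeR adjusted p = 0.689). The log2 fold change of lncRNA:roX1 was 0.18, turned to -0.27 without fat body control replicate 1, and was called with edgeR without control replicate 2 (0.90, adjusted p = 0.0343) and with library size only (2.58, adjusted p = 5.30e-04). Its edgeR and DESeq2 adjusted p lay between 5.30e-04 and 0.860 over the alternatives.

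Markers of other tissues also differed between brain and fat body. Hemocyte genes were lower in brain, 14 of 16 with 0 higher and a median of -4.24 (adjusted p = 6.99e-04; adjusted p = 0.275 with an estimated correlation). The collagen gene Col4a1 (FBgn0000299) stood at 1363 ± 112.7 CPM in fat body and 19.9 ± 8.33 CPM in brain. Whether these transcripts came from hemocytes or from fat body cells cannot be told from the counts. Eye disc genes were higher in 12 of 15 members and lower in 1 (median 5.16, or 4.44 with 3 members at their bound; adjusted p = 0.00116; adjusted p = 0.260 with an estimated correlation), and imaginal disc genes in 12 of 17 and 1 (median 3.38; adjusted p = 0.00415; adjusted p = 0.260 with an estimated correlation). Malpighian tubule genes were higher in 7 of 12 members and lower in 2 (median 4.30; adjusted p = 0.0359; adjusted p = 0.473 with an estimated correlation). This camera call was lost without brain replicate 1 (median 2.06, adjusted p = 0.105), brain replicate 2 (median 2.52, adjusted p = 0.0750) or fat body control replicate 2 (median 3.44, adjusted p = 0.103), with an adjusted p of 0.0175 to 0.160 over the preset-correlation alternatives. The lists of midgut (1 of 10 higher, 8 lower, median -3.90, adjusted p = 0.0918), muscle (1 of 18 higher, 10 lower, median -2.02, adjusted p = 0.156) and cuticle (3 of 13 higher, 6 lower, median -1.97, adjusted p = 0.524) did not pass camera. With library size only the muscle and cuticle medians were 0.36 and 0.40. Without brain replicate 1 the muscle list was called (median -2.51, camera adjusted p = 0.0294, and 0.0270 to 0.291 over the alternatives), and without brain replicate 2 the midgut list (median -3.86, adjusted p = 0.0497, and 0.00146 to 0.133). Lists of ring gland (6 of 10 higher, 3 lower, median 4.42, or 3.20 with 1 member at its bound, camera adjusted p = 0.871) and trachea (3 of 8 higher, 0 lower, median 1.52, adjusted p = 0.238) did not pass. Nor did salivary gland (1 of 13 higher, 0 lower, median -4.83, camera adjusted p = 0.952) and male germline (6 of 17 higher, 4 lower, median 0.48, adjusted p = 0.890). Without fat body control replicate 1 the salivary gland median turned to 4.08 (camera adjusted p = 0.291, and 0.0424 to 0.977 over the alternatives), with Sgs7 going from -5.11 to 4.08 and Sgs5 from -5.07 to 3.70. Camera ranked the salivary gland list upwards although its median and mean (-3.465) were negative, the heat shock list downwards although its median and mean (0.12) were positive, and the male germline list upwards although its mean was -0.06.

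The preset-correlation calls of 25 lists stood against 0 with an estimated correlation. Camera with an estimated correlation also missed a simulated list known to change (adjusted p = 0.0680). The simulated genes were drawn independently, so the simulation cannot show whether preset-correlation calls hold for correlated lists. Estimated correlations of the called lists ran from -0.08 for larval serum proteins to 0.83 for the respiratory chain. The larval serum, glia and imaginal disc lists had estimated correlations of -0.0839, 0.00606 and -0.00432, under the preset 0.01, and still lost their calls. For these lists a correlation above the preset value is argued against as the reason. A second reading with limma's fry called 30 lists, 24 of the 25 called by camera among them, and not the respiratory chain (adjusted p = 0.0671). Fry tests a list against no change, while camera tests it against the other genes. With 70.0% of all genes changed, the fry calls do not bear on a difference from the other genes. Adjusted over the list alone, the counts of higher and lower members equalled those over all genes except for 2 lower neuroblast genes, 53 lower cytochrome P450 genes and 24 higher heterochromatin genes. The authors' deposited results held 5328 genes with an adjusted p under 0.05, 2747 higher and 2581 lower in brain. Of these, 5306 were called with edgeR, all in the same direction. The split of calls rested on the scaling: with library size only 8757 genes passed and 86.5% of them were higher in brain, against 50.7% with TMM, and of 6167 genes called with both 4741 had the same direction.

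The second comparison asked whether raising larvae on 4-HT altered transcript levels in fat body. Larvae of both groups came from the lines with the 4-HT-dependent intein. An effect of 4-HT itself and one of the Dam proteins that depend on it therefore cannot be told apart here. Of the abundant fat body genes, Lsp2 stood at 251177 ± 864.5 CPM with 4-HT and 245461 ± 36169 CPM in control, and Lsp1alpha (FBgn0002562) at 29332 ± 3732 and 44519 ± 17100 CPM. Fbp1 (FBgn0000639) took 12.1% and 4.02% of the counts in the 4-HT libraries and 8.12% and 9.23% in control. None of the 11 larval serum protein genes passed. With edgeR 0 of 10029 genes passed, the smallest adjusted p was 0.284, and 596 genes had an unadjusted p under 0.05 against 501.5 by chance, 213 higher and 383 lower with 4-HT. DESeq2 on the same counts called 43 genes, 23 higher and 20 lower, and 28 on the 4 fat body libraries alone. The authors' deposited results held 3 genes under an adjusted p of 0.05, all lower with 4-HT: ItgaPS4, CG1208 and CG8870. Both replicates of one group lay above both of the other for 30.0% of tested genes, against 33.3% by chance.

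The 7 genes described here were chosen after their values were seen, among the 15 that DESeq2 called both with and without control replicate 1, and are not the 7 largest differences of the 43. Among those higher with 4-HT were sev (FBgn0003366), the receptor tyrosine kinase gene of R7 photoreceptor fate, at 70.4 and 27.8 CPM against 3.17 and 2.69 CPM in control, and Arc1 (FBgn0033926), at 1941 and 4833 CPM against 225.5 and 61.3 CPM. The odorant-binding protein gene Obp49a (FBgn0050052) stood at 19.5 and 69.7 CPM against 3.43 and 2.58 CPM. Lower were Sodh1 (FBgn0024289), a sorbitol dehydrogenase gene, at 12.7 and 15.0 CPM against 90.75 and 55.5 CPM, and CG8870 (FBgn0038144), at 8.17 and 8.26 CPM against 29.0 and 24.6 CPM. So were the integrin gene ItgaPS4 (FBgn0034005), at 2.87 and 4.675 CPM against 14.6 and 17.55 CPM, and CG1208 (FBgn0037386), at 4.635 and 7.92 CPM against 23.7 and 32.2 CPM. DESeq2 adjusted p was 2.84e-14 for sev, 3.34e-11 for Arc1, 4.50e-08 for Obp49a, 4.49e-10 for Sodh1, 2.68e-08 for CG8870, 1.26e-04 for ItgaPS4 and 1.99e-04 for CG1208. The edgeR adjusted p was 0.284 for sev, Sodh1 and CG8870 and 0.411 to 0.529 for the other 4. Without fat body control replicate 1 DESeq2 called 33 genes, 15 of which were among the 43, these 7 included. On simulated data DESeq2 made 33 false calls among 9829 unchanged genes of this comparison and edgeR 12 among 9629. Beside its false calls DESeq2 recovered 5, 24, 44 and 49 of 50 genes changed 1.5-fold, 2-fold, 4-fold and 16-fold. At these fold sizes edgeR recovered 1, 14, 41 and 47. The false share of all simulated calls was thus above the adjusted p threshold of 0.05 with both tools, and higher with DESeq2. The number of false calls depends on how many genes truly change, so it does not carry over to the 43 calls.

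**Figure D2:**
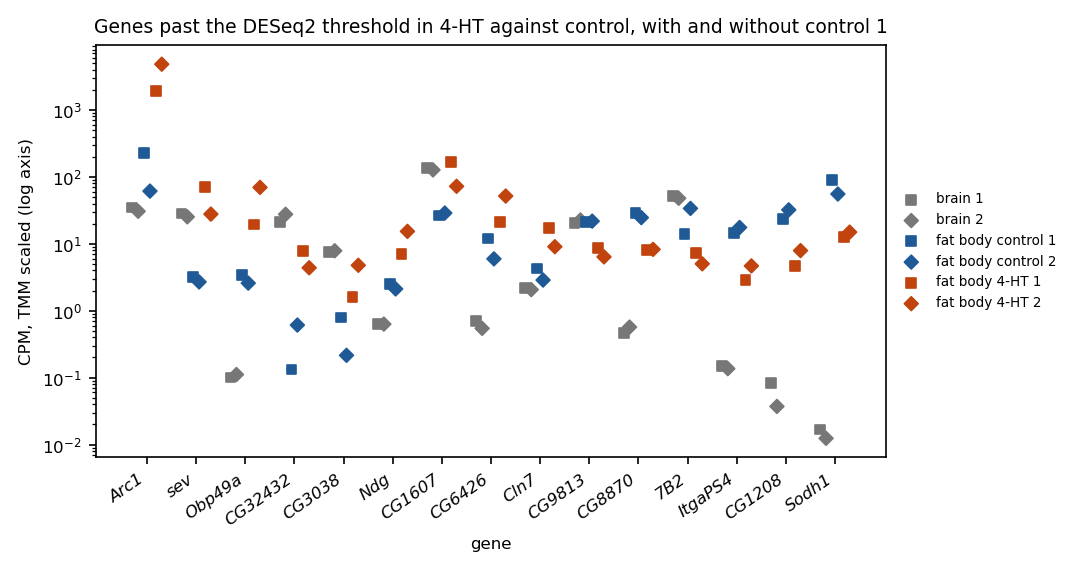
TMM-scaled CPM on a log axis in each of the 6 libraries for the 15 genes that DESeq2 called between 4-HT and control fat body both with and without control replicate 1; squares are replicate 1 and diamonds replicate 2. Arc1 and sev lie highest above control, with sev at 70.4 and 27.8 CPM against 3.17 and 2.69 CPM.

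Which genes edgeR called changed when single fat body libraries were left out. Such a fit leaves a lone library in a group, and the replicate spread of that group drops out. Added calls in these fits therefore do not show that the library left out had hidden a change. Without control replicate 1 edgeR called 5 genes, of which kirre, KCNQ, Sodh1 and 7B2 were lower and CG13501 higher with 4-HT. Without control replicate 2 it also called 5, all lower: Sodh1, BBS4, Ppn, CG32750 and dao. The count was 20 genes without 4-HT replicate 1 and 38 without 4-HT replicate 2. With every gene that had a count, edgeR called Sodh1 (log2 fold change -2.37, adjusted p = 0.0241) and CG8870 (log2 fold change -1.68, adjusted p = 0.0382). The gene sev passed edgeR without 4-HT replicate 1 (log2 fold change 3.26, adjusted p = 0.00265) and without 4-HT replicate 2 (log2 fold change 4.60, adjusted p = 8.99e-05), with 2.84e-14 (DESeq2) to 0.9998 (edgeR without the brain libraries) over the alternatives.

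Detoxification and stress genes did not move as groups with 4-HT. No member passed edgeR among 62 cytochrome P450 genes (median 0.08, camera adjusted p = 0.449), 38 glutathione transferase and UDP-glycosyltransferase genes (median -0.16, adjusted p = 0.449) or 23 xenobiotic regulators and transporters (median 0.14, adjusted p = 0.384). The same held for 18 heat shock genes (median 0.11, camera adjusted p = 0.890), 19 endoplasmic reticulum stress genes (median 0.01, adjusted p = 0.914) and 20 sterol genes (median 0.06, adjusted p = 0.275). The glutathione transferase list was called higher by camera without control replicate 1 (median 0.27, adjusted p = 0.0336) and lower without control replicate 2 (median -0.43, adjusted p = 0.00230) or 4-HT replicate 2 (median -0.47, adjusted p = 0.0494), with 0.00230 to 0.5905 over the alternatives. The P450 list was called higher by camera without 4-HT replicate 1 (median 0.32, adjusted p = 0.00222, and 0.00222 to 0.7405 over the alternatives), and the xenobiotic list too (median 0.17, adjusted p = 0.0407, and 0.0407 to 0.874). Cyp4p2 (FBgn0033395) stood at 151 ± 43.8 CPM with 4-HT and 61.7 ± 1.98 CPM in control (log2 fold change 1.30; edgeR adjusted p = 0.699, DESeq2 adjusted p = 0.0109, and 0.300 without control replicate 1). Of the genes fused to Dam, brm stood at 73.5 ± 10.5 CPM with 4-HT and 66.4 ± 8.68 CPM in control, and Pc at 6.02 ± 0.329 and 5.86 ± 0.347 CPM. The HP1 gene stood at 31.15 ± 3.58 and 33.4 ± 3.13 CPM, and MRG15 at 16.8 ± 0.273 and 14.1 ± 1.31 CPM. The ecdysone receptor gene EcR stood at 255 ± 51.5 and 243 ± 111 CPM.

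The muscle and hemocyte lists were called lower with 4-HT by camera, with 0 members passing edgeR over all genes tested. DESeq2 called 1 hemocyte gene over all genes, atilla (log2 fold change -2.07, adjusted p = 0.0196), and not without control replicate 1 (adjusted p = 0.864). For muscle 0 of 18 members passed edgeR and the median was -1.19 (camera adjusted p = 7.23e-08; adjusted p = 0.731 with an estimated correlation), for hemocytes 0 of 16 and -0.92 (adjusted p = 9.50e-06; adjusted p = 0.731 with an estimated correlation). The summed level of the muscle list was not lower, at 452.6 and 776 CPM in control and 840.6 and 432.4 CPM with 4-HT, and its most abundant member bt (FBgn0005666) stood at 452 ± 269.8 CPM with 4-HT and 414.5 ± 234.6 CPM in control. The hemocyte list summed to 2681 and 2908 CPM in control and 2152 and 2228 CPM with 4-HT. Much of these sums came from 2 genes that do not stand for the whole list. Col4a1 stood at 1363 ± 112.7 CPM in control and 1059 ± 73.54 CPM with 4-HT, and vkg at 648.9 ± 47.97 and 446.2 ± 23.45 CPM. With limma's fry 0 lists were called in this comparison (fry adjusted p = 0.780 to 0.963 over all lists), and none of the 8 called by camera passed (fry adjusted p = 0.780 to 0.916). The muscle and hemocyte camera calls held without each of the 4 fat body libraries, and without control replicate 1 the medians were -0.53 and -0.24 (camera adjusted p = 0.00140 and 0.0336). Over the preset-correlation alternatives the adjusted p of camera lay between 2.38e-10 and 0.00244 for muscle and between 3.34e-10 and 0.0338 for hemocytes. Adjusted over the list alone, 1 hemocyte gene passed edgeR, also atilla (FBgn0032422), a lamellocyte marker, at 0.993 and 1.91 CPM with 4-HT against 6.73 and 5.635 CPM. The lipid list was called higher by camera, with 0 of 16 members passing edgeR, a median of 0.32 and sums of 7748 and 7498 CPM in control and 8372 and 12035 CPM with 4-HT (adjusted p = 7.29e-05; adjusted p = 0.819 with an estimated correlation). The ATP citrate lyase gene ATPCL (FBgn0020236) stood at 822 ± 255 CPM with 4-HT and 357 ± 89.1 CPM in control (edgeR adjusted p = 0.835). The lipid call was lost without 4-HT replicate 2 (median 0.02, camera adjusted p = 0.414), with 4.49e-08 to 0.414 over the alternatives. The cuticle list was called lower by camera, with 0 of 13 members passing edgeR and a median of -0.89 (adjusted p = 0.0253; adjusted p = 0.731 with an estimated correlation), a call lost without control replicate 2 (median -0.11, adjusted p = 0.266) and without 4-HT replicate 1 (median -0.46, adjusted p = 0.378), with 0.00142 to 0.378 over the alternatives. Its summed level was not lower, at 7968 and 10087 CPM in control and 10759 and 8625 CPM with 4-HT, and its most abundant member Cpr49Ac stood at 9673 ± 1516 CPM with 4-HT and 8996.5 ± 1492 CPM in control.

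Salivary gland, mitochondrial genome, DNA replication and mitosis lists were also called lower with 4-HT, in calls that were lost without fat body control replicate 1, the library with 2032.5 CPM of salivary gland transcripts. The salivary gland median was -8.00, or -7.99 with 1 member at its bound (adjusted p = 7.23e-08; adjusted p = 0.819 with an estimated correlation), and 0.47 without this library (adjusted p = 0.741, and 4.62e-18 to 0.741 over the alternatives). Adjusted over the list alone, 1 salivary gland gene passed edgeR, the forkhead gene fkh (FBgn0000659), at 0.221 and 0.223 CPM with 4-HT against 1.65 and 0.897 CPM, and DESeq2 called fkh and ng3 over all genes (adjusted p = 0.00200 and 5.49e-04), and neither without control replicate 1 (adjusted p = 0.0910 and 1). For mitochondrial genome transcripts the median was -0.58 (0 of 14 passing; adjusted p = 4.30e-05; adjusted p = 0.819 with an estimated correlation), and -0.14 without control replicate 1 (adjusted p = 0.325) and -0.32 without 4-HT replicate 2 (adjusted p = 0.169, and 3.11e-10 to 0.325 over the alternatives). For DNA replication it was -0.40 (0 of 23; adjusted p = 0.00119; adjusted p = 0.821 with an estimated correlation), and -0.09 without control replicate 1 (adjusted p = 0.549) and -0.33 without 4-HT replicate 2 (adjusted p = 0.0793, and 5.79e-05 to 0.549 over the alternatives). For mitosis it was -0.57, or -0.62 with 1 member at its bound (0 of 26; adjusted p = 0.00651; adjusted p = 0.838 with an estimated correlation), and 0.15 without control replicate 1 (adjusted p = 0.457) and -0.08 without 4-HT replicate 2 (adjusted p = 0.874, and 4.75e-07 to 0.874 over the alternatives).

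**Figure D3:**
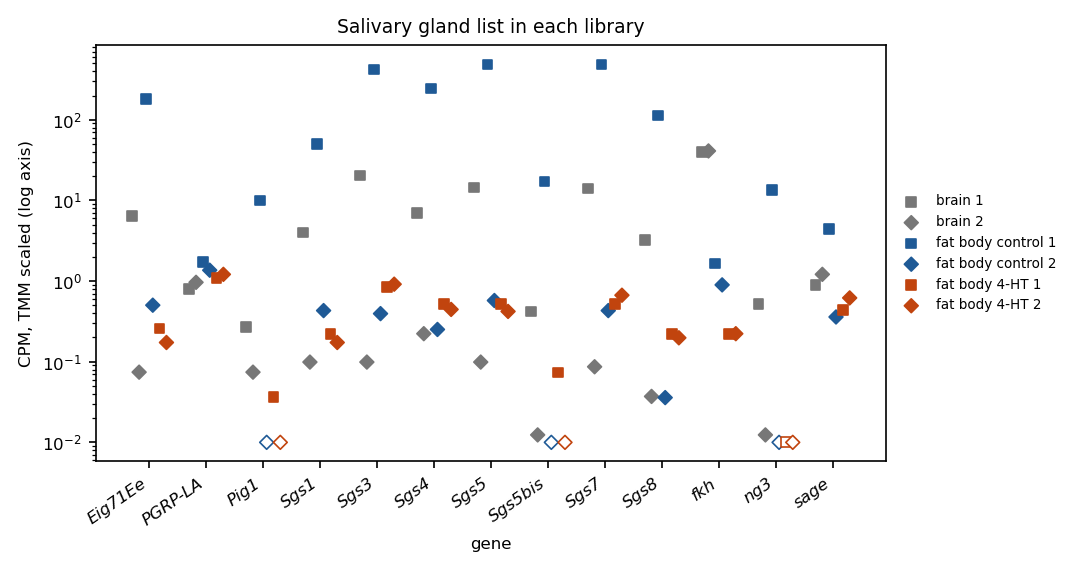
TMM-scaled CPM on a log axis of the 13 tested salivary gland genes in each of the 6 libraries; open symbols mark values under 0.01 CPM, drawn at 0.01. Glue protein genes such as Sgs3 and Sgs5 stand at 421 and 486 CPM in fat body control replicate 1 and under 1 CPM in the other fat body libraries.

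The remaining lists had 0 members past the edgeR threshold over all genes tested and were not called with 4-HT, while DESeq2 called the eye disc gene sev (adjusted p = 2.84e-14). Their medians were -0.04 for larval serum proteins, -0.07 for carbohydrate and amino acid metabolism, 0.04 for immunity, 0.08 for insulin and nutrient response, 0.13 for ecdysone response, and 0.03 for glia. The median was -0.11 for neuronal genes, -0.33 for neurotransmitter genes, -0.27 for neuroblast genes (-0.60 with 3 members at their bound), 0.27 for Hox genes (0.19 with 1 member at its bound) and -0.00 for Polycomb group genes. For heterochromatin genes the median was 0.06, for dosage compensation 0.05, for ribosomal proteins 0.10 and for the respiratory chain 0.13. Among markers of other tissues it was -0.25 for male germline (-0.46 with 1 member at its bound), 0.63 for midgut (0.58 with 1 at its bound), -0.12 for ring gland (-0.27 with 2 at their bound), -0.43 for eye disc (-0.65 with 4 at their bound), 0.22 for imaginal disc, -0.34 for Malpighian tubule and -0.55 for trachea. Adjusted over the list alone, 1 eye disc gene passed, sev. Calls appeared when single libraries were left out. Without control replicate 1 camera called midgut (median 1.54, adjusted p = 0.0248), respiratory chain (0.35, 2.11e-09), neuroblast (-0.26, 0.00140) and neuronal lists (-0.25, 0.0336). Without control replicate 2 it called insulin (0.24, 0.0462), male germline (-1.095, 7.18e-06) and imaginal disc lists (0.45, 0.0349). Without 4-HT replicate 1 it called male germline (-1.06, 0.00707), respiratory chain (0.27, 3.92e-04), ribosomal protein (0.25, 5.62e-04), neuroblast (-1.02, 6.90e-07), neuronal (-0.38, 4.38e-04) and neurotransmitter lists (-0.79, 0.0252). Without 4-HT replicate 2 it called ecdysone (0.24, 0.00720) and imaginal disc lists (0.23, 0.00888). Median and mean differed in sign for immunity (mean -0.23), glia (-0.15), endoplasmic reticulum stress (-0.05) and the respiratory chain (-0.01), and camera ranked the eye disc and Polycomb lists upwards although their medians were not positive.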

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

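Tests chosen only after the result was seen were legacy=FALSE, the DESeq2 fits on 4 libraries and without fat body control replicate 1, the crossed block, the upper quartile and library size settings for lists, and the alternatives for shared calls with the authors. In the tissue comparison, named genes kept their side of the threshold in 1980 gene and setting pairs, with the same direction where called. They passed only in the alternative in 10, lost a main call in 20 and reversed a main call in 8. Genes uncalled in both fits could change sign within the 1980 pairs, as Sgs7 did without fat body control replicate 1 (-5.11 to 4.08). The pairs include legacy=TRUE, which equals the main fit. All 8 reversals came with library size only, where no scaling factor beyond library size was applied. Log2 fold changes became 1.63 for Npc1a, 0.65 for Vha55, 0.22 for RpL5, 0.25 for RpLP1, 0.64 for RpLP2, 0.90 for ND-B14.5A, 1.00 for ND-19 and 0.41 for EcR. Called genes in the tissue comparison numbered 5688 to 6568 without single libraries and 5962 to 8757 over the other settings, against 7018. In this comparison 25 lists were called with the preset correlation and 0 with an estimated correlation. A correlation above the preset value is argued against for the larval serum, glia and imaginal disc lists, and the cause was not tested further.

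In the 4-HT comparison edgeR called 0 genes, with 596 at an unadjusted p under 0.05, and 43 were called by DESeq2, 28 by DESeq2 on the 4 fat body libraries and 33 by DESeq2 without fat body control replicate 1. Every gene with a count gave 2 calls in edgeR, and fits without single libraries gave 5 to 38 (5 without either control replicate, 20 without 4-HT replicate 1, 38 without 4-HT replicate 2). The causes of these differences were not tested. Calls shared with the authors' 3 genes numbered 0 in edgeR, 1 with every gene with a count, 3 in each of the 3 DESeq2 fits, and 0 to 3 without single libraries. With 4-HT 8 lists were called, against 0 with an estimated correlation, 13 with library size only and 7 to 15 without single libraries (15 without 4-HT replicate 1), and the cause was not tested. The mitosis list had medians of -1.33 to 0.15 without single libraries, and reversed to 0.15 without fat body control replicate 1, the library high in salivary gland transcripts. Named genes stayed uncalled in 1054 pairs and passed only in the alternative in 8. Uncalled genes could change sign, as EcR did without fat body control replicate 1 (0.07 to -0.33). Lists kept their side of the threshold in 415 pairs, with the same camera direction where called. Of the other pairs, 29 were called only in the alternative, 19 were lost and 1 reversed in the direction of camera. The salivary gland median also turned, from -8.00 to 0.47 without fat body control replicate 1, while camera still ranked it downwards.

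A replicate block gave 6658 calls in the tissue comparison and 0 in the 4-HT comparison with edgeR. Deviations of replicates 1 and 2 correlated between groups at 0.188, -0.137 and -0.0900, and a crossed block also gave 0 gene calls with 4-HT. List calls with 4-HT changed under both blocks: the replicate block added the respiratory chain (9 lists), and the crossed block added the respiratory chain and ribosomal proteins and lost mitosis and cuticle (8 lists). With 2 libraries per group, 28.0% of simulated 2-fold changes were recovered by edgeR in the 4-HT comparison, and 48.0% by DESeq2, so either tool can miss changes of that size. These shares depend on how many genes truly change and do not carry over to the data. With edgeR 94.0% of simulated 16-fold changes were recovered, while sev, measured 16.85-fold higher, was not called. Genes with few counts in a group have ratios limited by depth, as in the interval of 175 to 38458 for slp2.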

Other observations

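Hox genes split by tissue. The anterior genes pb, Dfd and Scr were higher in brain, with log2 fold changes of 3.285, 4.24 and 3.83, and lab was at least 11.5-fold higher, at 0.796 ± 0.0813 CPM (mean ± SD, n = 2). The trunk and posterior genes Antp, Ubx, abd-A and Abd-B were higher in fat body, with log2 fold changes of -6.92, -7.935 and -9.73 for the first 3. Abd-B stood at 18.2 ± 2.95 CPM in fat body and had 2 counts in brain, a ratio of 1320 with a 95% counting interval of 364 to 10920. The brain samples excluded the ventral nerve cord, where trunk Hox genes are expressed. With 4 of 8 members higher and 4 lower, also with library size only, the list had a median of -1.82 (0.56 with library size only) and was not called (camera adjusted p = 0.0826; adjusted p = 0.297 with an estimated correlation). Without fat body control replicate 1 it was called (median -2.005, camera adjusted p = 0.0187), and without control replicate 2 too (median -1.71, adjusted p = 0.0209), with 0.00542 to 0.194 over the alternatives.

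Single members went against their lists in the tissue comparison, named after their values were seen. Among neuronal genes Syt1 was lower in brain (-2.61), among neuropeptide genes svr (-3.28) and among neuroblast genes svp (-3.41), a gene also known in other larval tissues. Among metabolic and detoxification genes Ldh (3.02), Cyp4g15 (8.63) and GstZ2 (8.12) were higher in brain. The insulin pathway genes chrb (5.39), scyl (2.76) and Sdr (6.19) and the lipophorin receptor genes LpR1 (3.26) and LpR2 (2.68) were also higher in brain.

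Tests chosen only after the result was seen were those of the salivary gland transcripts, of the eye disc list, of the expressed neighbours of sev, of sev without single libraries and of the list calls without fat body control replicate 1, while the test of reads from the neighbours of sev was set before. Salivary gland transcripts were high in fat body control replicate 1, with 11 of 13 tested members over 4-fold above every other fat body library, including the transcription factor gene sage (4.42 CPM against 0.359 to 0.618 CPM). This may reflect salivary gland RNA in this library. An effect of 4-HT lowering these transcripts is argued against by control replicate 2, whose sum over all list members, tested or not, was 1.05 times the mean of the 4-HT libraries. Mixing with a brain library is argued against because the sum was 18.0 times that of the higher brain library.

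The gene sev was higher in both 4-HT libraries, at 70.4 and 27.8 CPM against 3.17 and 2.69 CPM. Eye disc or brain tissue in the 4-HT libraries is argued against by the other 14 tested eye disc genes, whose median log2 fold change was -0.44. A rise of an expressed neighbouring gene is argued against by CG2076 (0.30), CG15203 (0.09) and Vago (0.08), while the test of reads from a neighbouring or overlapping gene gave 1.10 at its highest, for CG1537 at 0.0359 and 0.0926 CPM, and the overlapping antisense gene asRNA:CR44358 was not analysed here and stays open. That 4-HT feeding raised sev also stays open, since sev passed in 2 of the 4 edgeR fits that left out 1 fat body library and not with all 6 libraries, while it passed in each of the 3 DESeq2 fits (log2 fold changes 4.08, 4.08 and 4.16, adjusted p = 2.84e-14, 1.67e-13 and 2.66e-09). The 2 edgeR fits in which sev passed each had a lone 4-HT library, so the spread between the 4-HT replicates was not counted in them. Reads of the antisense gene and an effect of 4-HT cannot be told apart, since the antisense gene has no value here. Nor can an effect of 4-HT itself be told apart from one of the Dam proteins with the 4-HT-dependent intein.

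Of the 8 lists called between 4-HT and control fat body, 4 were called in the same direction by camera without fat body control replicate 1, so this library alone is argued against as the source of all 8 calls. Left out in the same way, control replicate 2 and 4-HT replicate 1 left 7 calls each, and 4-HT replicate 2 left 4. The DNA replication, mitosis and mitochondrial genome calls were lost without control replicate 1 and also without 4-HT replicate 2, and the salivary gland call was lost without control replicate 1 and made without each of the other 3 libraries. The muscle and hemocyte medians were nearer 0 without control replicate 1, at -0.53 and -0.24 against -1.19 and -0.92. What lay behind the separate list calls was not tested, and no biological explanation was tested for them.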
